A study of Homo sapiens with 6 samples.

How the data were processed

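RNA was sequenced in 6 libraries from CT27, an established human trophoblast stem cell line of placental origin: 3 libraries of cells kept in the stem state (HTS in the labels) and 3 of cells differentiated towards extravillous trophoblast (EVT), the invasive cell type of the placenta. Per the labels' protocols, cDNA was made with the SMART-Seq v4 kit and read as 101 bp read pairs on a NovaSeq instrument. The sources used here do not say whether replicates of a group were separate differentiations, separate dishes or repeated libraries of 1 RNA.

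The authors' count table holds 1 count per gene and library, in whole numbers, and was used as it was deposited. Per the submitters' processing notes, which list tools without role or order, the software was bcl2fastq, STAR 2.6.1c, RSEM 1.3.1 and DESeq2 with build GRCh38. RSEM gives estimated counts, so the deposited counts may be rounded estimates, a point the sources leave open. Annotation release, aligner settings and the way reads shared between genes were counted are not given in the sources used here. The authors' deposited comparison table gives, per the file headers, a log2 fold change with its standard error, a p-value and an adjusted p-value for each gene, in the columns that DESeq2 writes. Every absolute log2 fold change in the authors' deposited table is above 1.5 and its largest adjusted p-value is 0.0497, so it holds the genes past both cutoffs. The 1.5 in its title therefore stands on the log2 scale.

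The count table has 58395 lines, and 1705 of them carry 1 of 162 symbols that stand on more than 1 line; those lines were kept apart. Symbols of 99.0% of the lines were found in GENCODE 29 on GRCh38, from which coordinates, counted from 1, and overlaps between exons were taken. Totals were 36012312, 23776239 and 41615480 counts in HTS replicates 1, 2 and 3, and 22093103, 24460072 and 26482207 counts in EVT replicates 1, 2 and 3. XIST, its antisense gene and Y-linked genes were left out of the written values.

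Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, with a minimum count of 10 and a minimum total of 15, and libraries were scaled by TMM factors of 1.09, 1.09 and 1.08 in HTS and 0.907, 0.911 and 0.938 in EVT. EVT was compared with HTS by the two-sided quasi-likelihood F-test with robust dispersion and no covariate, which left 4 residual degrees of freedom. P values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A positive log2 fold change is higher in EVT. Levels are CPM, that is counts relative to the TMM-scaled library size, as mean ± SD of n = 3 libraries, and folds without an SD are fitted folds whose standard error (SE) is on the log2 scale. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group. Such floors cover counting error only.

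A set of 42 gene lists, 11 of cell type markers and 31 of pathways, was written before the data were examined, as were the comparison, its test, the alternatives (except 1 named below) and the rule for naming genes. Of 1244 list entries, 1235 matched the count table, 30 of them by an older or synonymous symbol. Lists with at least 5 measured members were compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 39 lists tested. The tests were repeated with a correlation estimated for each list, and fry tested whether a list's own genes moved on balance one way.

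The genes named came from a rule with several parts. They were the 10 largest rises and 10 largest falls among changed genes with at least 20 CPM in all 3 libraries of the higher group and no overlap between groups. To these came a fixed set of 20 trophoblast genes, whatever their values, and up to 4 members per list with the largest absolute change among those past the threshold with a mean of at least 5 CPM. Pseudogenes, XIST and Y-linked genes were never named. A gene outside this rule is marked as chosen after its values were seen.

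Alternatives were DESeq2 size factors or library totals in place of TMM, no low-count filter or at least 1 CPM in 3 libraries, and DESeq2 1.42.0 or limma-voom as the test. Further ones were each library left out in turn, the replicate number as a block, a threshold of 0.01, libraries thinned to the smallest total, the 20 most abundant and all mitochondrial genes left out, and a test against a fold of 1.5 (glmTreat). After the closeness of the libraries was seen, 1 more was added, in which the HTS libraries were summed to 1 and EVT replicates 1 and 2 were summed to 1.

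The procedure was tested on simulated counts for the 17688 genes, drawn with the totals of these libraries and the mean of each gene over both groups. Far fewer genes were changed in the simulation than in the real comparison, where 74.8% changed. Its recovery and its share of false calls may therefore not carry over. In the simulated EVT and HTS comparison, 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. Of those that passed the count filter, edgeR recovered 53.8%, 79.1% and 95.2%, in that order. Of its 171 calls, 23 were genes simulated without a change, a larger share than the threshold of 0.05 allows for. With no simulated change, 2 of 17688 genes and 0 of 39 lists were called. With the extravillous list raised, that list was found, and 1 other list was called with it.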

Results

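Gene expression was measured by RNA sequencing in CT27 human trophoblast stem cells, in 3 libraries of the stem state (HTS) and 3 libraries of cells differentiated towards extravillous trophoblast (EVT). The libraries held between 22093103 and 41615480 counts each. The comparison of EVT with HTS asks which genes change when these stem cells are taken towards the invasive trophoblast lineage, and 17688 genes had enough counts to be tested. Anything else that differs between the groups, such as culture conditions, cannot be told apart from the change of state. Values are CPM, counts scaled to library size and composition, as mean ± SD, with n = 3 libraries per group throughout, and coordinates are from GENCODE 29 on GRCh38. In each gene list, the counts adjusted over the list alone were those given over all genes tested, unless both are stated. Genes named as a list's exceptions were singled out after their values were seen.

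The EVT libraries carried high levels of extravillous trophoblast genes. HLA-G, the class I molecule displayed by invasive trophoblast (chromosome 6, 29826967 to 29831125), rose 37.4-fold, from 8.77 ± 0.615 to 328 ± 90.7 CPM (log2 fold change 5.23, SE 0.218, adjusted p = 5.34e-07). MMP2, a gelatin-degrading metalloproteinase (chromosome 16, 55389700 to 55506691), rose 36.0-fold, from 52.6 ± 0.815 to 1895 ± 16.7 CPM (adjusted p = 6.05e-10). Genes of the syncytiotrophoblast, the hormone-secreting layer of the placenta, rose as well. The hormone subunit CGA (chromosome 6, 87085498 to 87095406) rose from 904 ± 9.60 to 28650 ± 4650 CPM, 31.7-fold (adjusted p = 1.79e-08). Stem-state genes fell, among them the transcription factor TEAD4 (chromosome 12, 2959330 to 3040673), from 127.5 ± 1.27 to 5.79 ± 0.474 CPM, 22-fold lower (adjusted p = 2.05e-09).

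Of the 39 measured extravillous trophoblast markers, 36 rose and 1 fell, with a median log2 fold change of 3.09. Camera placed the list above other genes (adjusted p = 1.86e-28; adjusted p = 0.057 with an estimated correlation). The largest rise in the list was that of ADAM12, a membrane metalloproteinase (chromosome 10, 126012381 to 126388455), from 0.431 ± 0.141 to 444 ± 150 CPM, 991-fold. The serine protease HTRA4 rose 254-fold, DIO2, which activates thyroid hormone, 244-fold, and FLT1, a receptor for vascular endothelial growth factor, 171-fold. ITGA1, the collagen-binding alpha-1 integrin (chromosome 5, 52787896 to 52959210), rose from 11.1 ± 0.813 to 301 ± 80.5 CPM, and ITGA5, the alpha chain of the fibronectin receptor, from 313 ± 3.56 to 1707 ± 192 CPM. ASCL2, a basic helix-loop-helix factor of trophoblast, rose 2.57-fold. The member that fell was TCF7L2 (log2 fold change −0.31), while PLAC8 at −0.16 and TGFBI at 0.68 did not pass. Of the 39, 26 stand in another list as well, such as those of proteases, matrix, integrins and WNT targets below, so these lists do not move independently of this one. In EVT replicate 3, 27 of the 39 members were higher than in both other EVT libraries (median log2 ratio 0.27). HLA-G, for one, was at 432 CPM there against 278 and 272.

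Of the 39 measured syncytiotrophoblast genes, 37 rose and 1 fell, with a median log2 fold change of 4.37. This list had the smallest p of the 39 tested with camera (adjusted p = 2.26e-57), and its call held with an estimated correlation (adjusted p = 0.0109). CSH1 and CSH2, which encode placental lactogen, had no count in the HTS libraries and reached 815 ± 319 and 332 ± 130 CPM in EVT. Against a floor of 3 counts over the HTS group, they were at least 30000-fold and at least 12200-fold higher. The pregnancy-specific glycoprotein PSG3 rose 199.5-fold, to 2124 ± 73.4 CPM, and INHA, the inhibin alpha subunit, rose 187-fold. CGB3, a beta subunit of chorionic gonadotropin (chromosome 19, 49022869 to 49024333), rose 71.7-fold to 7041 ± 1370 CPM, and the proteoglycan SDC1 rose 13.1-fold to 1560 ± 82.3 CPM. ALPP, placental alkaline phosphatase, fell (−0.72) and OVOL1 stood at 0.49 without passing. Of the 39, 21 were lower in EVT replicate 3 than in both other EVT libraries and 14 higher (median log2 ratio −0.09). The CGB, CSH and PSG genes have near-identical relatives, so that the split of reads between them is uncertain. CGA and the CGB genes together took 0.14% of the counts in each HTS library and 5.43%, 5.24% and 3.97% in EVT replicates 1, 2 and 3.

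Among 23 measured genes of trophoblast stem cells and villous cytotrophoblast, 16 fell and 5 rose, with a median of −1.04 (camera adjusted p = 2.66e-05; adjusted p = 0.057 with an estimated correlation). LRP2, the endocytic receptor megalin (chromosome 2, 169127109 to 169362685), fell 41.4-fold from 2591 ± 10.5 to 62.5 ± 3.37 CPM. ELF5, an ETS factor of trophoblast stem cells, fell from 8.09 ± 0.510 to 0.466 ± 0.188 CPM, and the epithelial adhesion molecule EPCAM fell from 239 ± 4.81 to 17.9 ± 7.0 CPM. TP63, a factor of epithelial progenitors (chromosome 3, 189631416 to 189897279), fell from 24.8 ± 0.824 to 6.01 ± 4.97 CPM (log2 fold change −2.01, SE 0.451, adjusted p = 0.00537). Of the 23, 14 were higher in EVT replicate 3 than in both other EVT libraries and 7 lower (median log2 ratio 0.14). EVT replicate 3 held 11.7 CPM of TP63 against 2.80 and 3.50 in the others, and without that library the log2 fold change was −2.96. TP63 no longer passed without the low-count filter, at −2.07. ITGA6, a laminin-binding integrin chain, fell 2.06-fold. LIFR, the receptor for leukaemia inhibitory factor, rose 10.8-fold to 1160 ± 205 CPM. The other members that rose were DUSP9, IGF1R, KRT8 and TINAGL1. The summed level of the list did not fall, at 13190 CPM in HTS and 14010 CPM in EVT.

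The 15 pan-trophoblast genes went both ways, with 7 up and 4 down and a median of 0.08, but 7 up and 7 down and −0.16 under scaling by library totals (camera adjusted p = 0.589). KRT7, a cytokeratin of trophoblast, was at 342 ± 2.22 CPM in HTS and 331 ± 14.8 CPM in EVT (log2 fold change −0.05, SE 0.0471, adjusted p = 0.378). The transcription factor GATA2 was at 1276 ± 2.67 and 1294 ± 144 CPM (0.02, SE 0.0781, adjusted p = 0.821). Under library totals KRT7 passed at −0.29 and GATA2 changed sign and passed at −0.23, and without EVT replicate 3 they passed at −0.08 and 0.11. Of the 15, 10 were lower in EVT replicate 3 than in both other EVT libraries (median log2 ratio −0.19). GATA3 fell 1.62-fold, KRT19 and VGLL1 also fell, and TFAP2C rose (log2 fold change 0.67). EGFR, the epidermal growth factor receptor, rose 4.98-fold and HAND1 fell 23.3-fold. Of 12 genes of the cell columns, the zone between villus and invasive cells, 7 fell and 1 rose (median −0.70, camera adjusted p = 0.0705; adjusted p = 0.299 with an estimated correlation). Among those that fell were the transcription factor SOX15 (4.83-fold), MYC (2.79-fold) and the receptor NOTCH1 (2.62-fold), and LPCAT1 rose. The cell column list passed the camera threshold without HTS replicate 1 (adjusted p = 0.0425), HTS replicate 3 (0.0463) or EVT replicate 3 (0.00176), with the replicate number as a block (0.037) and with summed libraries (0.0253), that is HTS to 1 and EVT replicates 1 and 2 to 1, an alternative chosen after their closeness was seen. The summed fit has a single HTS sample, so its spread comes only from EVT replicate 3 against the sum of the other two. At the preset correlation the range over its alternatives was 0.00176 to 0.126, and 8 of its 12 genes were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.33).

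**Figure D1:**
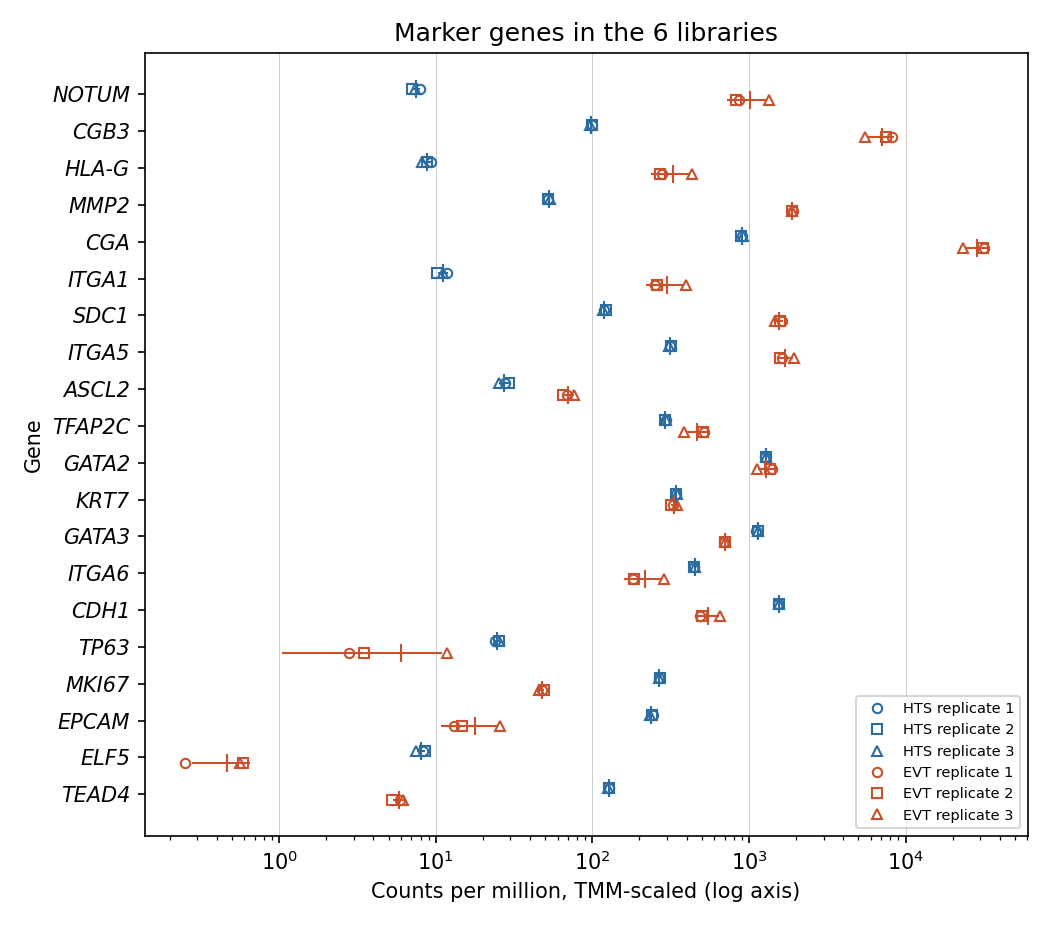
Scaled counts (CPM) on a log axis for 20 trophoblast marker genes in the 6 libraries, with HTS in blue and EVT in red, a symbol per replicate, and a vertical tick with a horizontal bar for mean ± SD of n = 3. NOTUM, CGB3, HLA-G, MMP2 and CGA lie far to the right in EVT, TEAD4, ELF5 and EPCAM far to the left, and KRT7 and GATA2 overlap between the groups.

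Genes of cell division fell in EVT. Of 55 measured genes of G2/M and mitosis, 53 fell and 1 rose, with a median of −2.44 (camera adjusted p = 3.42e-40). The call held with an estimated correlation (adjusted p = 0.0109), and the member that rose was RANGAP1. MKI67, which encodes the proliferation antigen Ki-67 (chromosome 10, 128096659 to 128126385), fell 5.64-fold, from 267 ± 2.61 to 47.5 ± 1.99 CPM. The mitotic kinases NEK2 and PLK1 fell 11.2-fold and 9.45-fold, and CENPA, the centromeric histone, fell 9.87-fold. Of 46 genes of DNA replication and the G1/S step, 41 fell and 2 rose (median −1.04, camera adjusted p = 1.43e-08; adjusted p = 0.298 with an estimated correlation). UHRF1, which helps carry DNA methylation through replication, fell 8.34-fold, and CCNE1, or cyclin E1, rose (0.84), as did CASP8AP2 (0.25). In EVT replicate 3, 32 of these 46 genes were below both other EVT libraries (median log2 ratio −0.16). The 19 cell cycle inhibitors and senescence genes went both ways, with 6 up and 10 down (median −0.26, camera adjusted p = 0.27), or 4 up and 11 down under library totals (median −0.51). CDKN1C, an imprinted inhibitor of cyclin-dependent kinases, rose 2.67-fold to 1964 ± 277 CPM and GADD45G rose 3.32-fold, while LMNB1, a lamin of the nuclear envelope, fell 5.30-fold. The summed level of the G2/M list was 3874 CPM in HTS and 1437 CPM in EVT.

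Epithelial junction genes fell, 19 of 28 against 7 that rose (median −0.64, camera adjusted p = 0.000438; adjusted p = 0.0739 with an estimated correlation). CDH1, or E-cadherin (chromosome 16, 68737225 to 68835548), fell from 1547 ± 7.45 to 547 ± 93.3 CPM, the tight junction protein cingulin (CGN) fell 11.2-fold and claudin 3 (CLDN3) fell 5.73-fold. Of 18 mesenchymal genes, 7 rose and 10 fell. The measures of this list differed in sign, with a median of −0.64, a mean of −0.38 and camera pointing up without passing (adjusted p = 0.575). Its fibrillin gene FBN1 rose 27.1-fold, and CTGF and CYR61, secreted matricellular proteins, fell 19.3-fold and 10.1-fold. In EVT replicate 3, 15 of the 18 mesenchymal genes were above both other EVT libraries (median log2 ratio 0.51). Without that library the log2 fold change was −4.96 in place of −4.27 for CTGF, and −4.41 in place of −3.68 for THBS1, another matricellular protein.

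Of 33 metalloproteinases and other proteases, 22 rose and 6 fell (median 0.62, camera adjusted p = 5.97e-07; adjusted p = 0.22 with an estimated correlation). Under library totals 19 rose and 7 fell (median 0.37). PAPPA, a protease that releases insulin-like growth factors from their binding proteins, rose 158-fold from 0.180 ± 0.0450 to 27.9 ± 4.48 CPM. Of the 33, 23 were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.24). Among 21 protease inhibitors, 10 rose and 7 fell (median 0.40, camera adjusted p = 0.31), or 9 and 8 under library totals (median 0.16). TFPI, an inhibitor of coagulation, rose 44.4-fold and SERPINE1, the plasminogen activator inhibitor, 7.37-fold. In EVT replicate 3, 18 of the 21 were above both other EVT libraries (median log2 ratio 0.45). Of 51 structural matrix genes, 25 rose and 18 fell (median 0.68, camera adjusted p = 0.0794; adjusted p = 0.649 with an estimated correlation), and 36 of them were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.29). LAMA4, a laminin chain (chromosome 6, 112108760 to 112254939), had no count in HTS and reached 98.6 ± 20.6 CPM, at least 3620-fold higher. The proteoglycans VCAN and BGN rose 35.5-fold and 30.4-fold. The matrix list passed the camera threshold under scaling by library totals (adjusted p = 0.0477), without EVT replicate 1 (0.0241), without EVT replicate 2 (0.0488) with the replicate number as a block (0.00894) and with summed libraries (0.00541). The range over its alternatives at the preset correlation was 0.00541 to 0.627, and under library totals 24 rose and 22 fell (median 0.44). Of 14 integrins, 7 rose and 6 fell (median 0.26, or 0.02 under library totals, camera adjusted p = 0.186), with ITGB3 10.1-fold and ITGAV 3.12-fold higher, and 9 of the 14 were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.28).

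**Figure D2:**
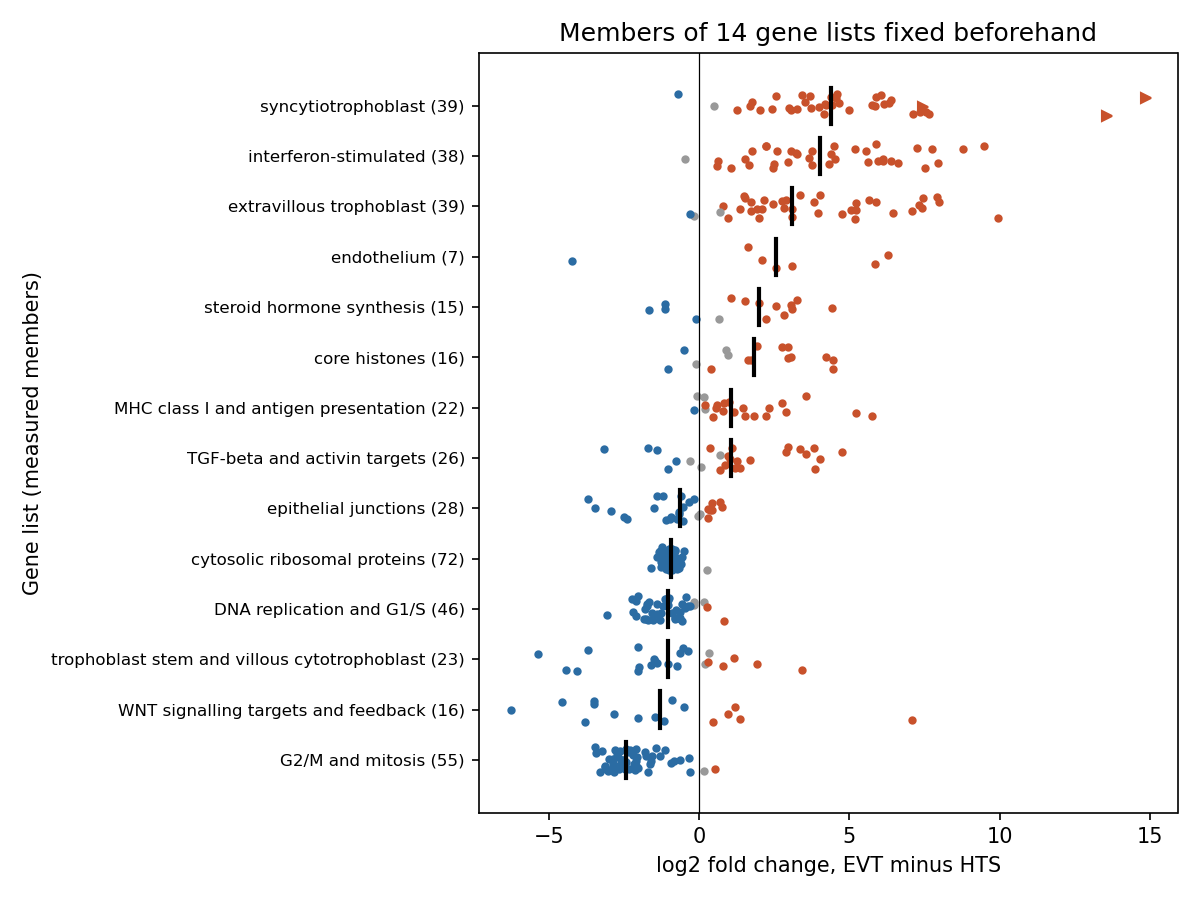
Log2 fold change of EVT over HTS for each measured member of 14 of the 39 gene lists tested, with the number of members in parentheses, red for higher and blue for lower in EVT, grey for genes that did not pass, triangles for lower bounds of genes with no count in HTS, and a black bar for the list median. List membership was fixed beforehand. The 14 lists drawn are a selection from the 22 that passed with camera at the preset correlation, and all other lists are not drawn. With an estimated correlation, only the syncytiotrophoblast and G2/M lists passed. The medians run from −2.44 for G2/M and mitosis to 4.37 for syncytiotrophoblast.

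Targets and feedback genes of WNT signalling fell, 11 of 16 against 5 that rose (median −1.32, camera adjusted p = 0.00287; adjusted p = 0.129 with an estimated correlation). CCND1, or cyclin D1, and the transcription factor TCF7 both fell 11.3-fold and ZNRF3, which removes WNT receptors, fell 14-fold. NOTUM, a secreted enzyme that inactivates WNT proteins (chromosome 17, 81952507 to 81961840), rose 135-fold to 1013 ± 290 CPM, and ASCL2, APCDD1, LGR4 and BMP4 rose too. The summed level of the WNT list rose, from 844.6 CPM in HTS to 1562 CPM in EVT. Of the 16, 10 were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.20). The TGF-beta and activin list holds ligands and receptors of the pathway as well as targets. Its genes rose, 18 of 26 against 5 that fell (median 1.04, camera adjusted p = 2.52e-05, or 0.0769 with an estimated correlation). Among them were FSTL3, which binds activin, at 16-fold and the co-receptor ENG at 10.3-fold higher. BAMBI, a decoy receptor, fell 8.96-fold, and ID1, ID2, INHBB and LTBP2 fell too. The YAP/TEAD list holds the factors and cofactors themselves, such as TEAD4, as well as targets. Its genes fell, 19 of 28 against 8 that rose (median −0.60, camera adjusted p = 0.0467, or 0.298 with an estimated correlation). That call was also lost with a filter of 1 CPM (0.0608), without EVT replicate 1 (0.054) or 2 (0.0607) and with the replicate number as a block (0.0733), in a range of 0.0138 to 0.0733 at the preset correlation. Of the 28, 17 were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.14), and the list's mean of log2(CPM + 1) was 5.42, 5.40 and 5.75 in EVT replicates 1, 2 and 3 against 6.13, 6.11 and 6.11 in HTS. In this list NT5E, an enzyme that makes adenosine, rose 55-fold and the TEAD cofactor VGLL3 rose 25.2-fold. In the NOTCH list, 6 of 18 genes rose and 7 fell, with a median of −0.04, a mean of 0.07 and camera pointing up without passing (adjusted p = 0.849). Under library totals 4 rose and 8 fell (median −0.28). The receptor NOTCH2 rose 3.77-fold. In the EGFR and MAPK feedback list, 9 of 27 rose and 13 fell, against 10 and 13 adjusted over the list alone. Its median was −0.30, or −0.55 under library totals, and its mean −0.26, with camera pointing up without passing (adjusted p = 0.755). Of the 27, 16 were lower in EVT replicate 3 than in both other EVT libraries (median log2 ratio −0.13). Its receptor ERBB2 rose 6.75-fold and the ETS factors ETV5 and ETV4 rose 5.90-fold and 5.35-fold.

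Interferon-stimulated genes rose, 37 of 38 with none falling and GBP2 not past the threshold (−0.47), with a median of 4.03 (camera adjusted p = 7.44e-12; adjusted p = 0.298 with an estimated correlation). OAS2, an antiviral nucleotide polymerase, rose 712-fold from 0.0789 ± 0.0359 to 54.8 ± 10.7 CPM, XAF1 rose 436-fold and IFI27 rose 154-fold. OAS1 rose 245-fold on 6 counts in all of HTS, and its log2 fold change of 7.94 became 8.77 without HTS replicate 1. The folds of OAS2 and XAF1 likewise rested on 8 and 5 counts in all of HTS, and that of IFI27 on 48. EVT replicate 3 held less of this group, with 32 of the 38 genes below both other EVT libraries (median log2 ratio −0.76). Genes of MHC class I and antigen presentation rose, 18 of 22 with RFX5 falling (median 1.06, camera adjusted p = 0.000102; adjusted p = 0.298 with an estimated correlation). The peptide transporter subunits TAP1 and TAP2 rose 7.47-fold and 6.76-fold, and the peptide-trimming enzyme ERAP2 4.97-fold. Of the 22, 17 were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.16). Of 21 immune checkpoint and immunomodulatory genes, 15 rose and 5 fell (median 1.48, camera adjusted p = 0.0189; adjusted p = 0.298 with an estimated correlation). Of the 21, 13 were higher in EVT replicate 3 than in both other EVT libraries and 6 lower (median log2 ratio 0.18). The checkpoint ligand PDCD1LG2 rose 43.6-fold and EBI3, a cytokine subunit, 14.2-fold. The cytokine IL6 (chromosome 7, 22725884 to 22732002) fell 50.8-fold from 38.9 ± 0.540 to 0.766 ± 0.170 CPM, and CSF1, LIF, LGALS1 and LGALS9 fell too.

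Steroid hormone synthesis genes rose, 10 of 15 with 4 falling (median 1.98, camera adjusted p = 2.9e-07; adjusted p = 0.0566 with an estimated correlation). CYP11A1, which makes pregnenolone from cholesterol, rose 21.2-fold to 1854 ± 157 CPM, CYP19A1, or aromatase, rose 8.32-fold to 2742 ± 442 CPM, and HSD11B2, which inactivates cortisol, rose 9.48-fold. The members that fell were FDXR, HSD17B12, SRD5A1 and STS. Among 21 angiogenic and vasoactive factors, 9 rose and 8 fell (median 0.50, or 0.26 under library totals, camera adjusted p = 0.0314; adjusted p = 0.22 with an estimated correlation). Its call was lost without EVT replicate 2 (adjusted p = 0.0821) and without EVT replicate 3 (0.437), in a range of 0.00887 to 0.437 at the preset correlation. ANGPTL4 rose 80.8-fold and the angiotensin-converting enzyme ACE2 rose 31.1-fold. FLT4, a receptor for lymphatic growth factors, was at 26.5, 27.5 and 6.25 CPM in EVT replicates 1, 2 and 3 against 0.208 ± 0.113 in HTS.

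Markers of other cell types were measured in part. Enough counts were present for 7 of 12 endothelial, 8 of 12 fibroblast and stromal and 6 of 10 amnion genes. Fewer were measured of the macrophage and leukocyte list (3 of 13) and the pluripotent stem cell list (3 of 10). Endothelial genes rose, 6 of 7 with 1 falling (median 2.55, camera adjusted p = 7.93e-06; adjusted p = 0.057 with an estimated correlation). CDH5, a cadherin of endothelial junctions, went from 304 ± 2.37 to 1784 ± 263 CPM, ESAM from 1.34 ± 0.191 to 106 ± 16.7 CPM and PECAM1 from 0.513 ± 0.119 to 29.4 ± 0.443 CPM. The endothelial receptor TIE1 fell (log2 fold change −4.25). Of 8 fibroblast and stromal genes, 3 rose and 4 fell. Their median was −0.44, or −0.68 under library totals, and their mean 0.04, with camera pointing down without passing (adjusted p = 0.845). COL1A2, a collagen I chain, fell from 1143 ± 11.9 to 232 ± 180 CPM, with 439 CPM in EVT replicate 3 against 130 and 125. Its log2 fold change of −2.30 became −3.16 without that library, and it no longer passed without the low-count filter, at −2.37. LUM, PDGFRA and PDGFRB also fell, COL3A1, COL6A3 and POSTN rose, and COL1A1 did not pass (−0.01). Of 3 macrophage and leukocyte genes, too few for a list test, CSF1R rose 2.32-fold, CD74 fell 6.33-fold and LAPTM5 also fell, at a median of −2.66. CSF1R no longer passed without the low-count filter (1.15 in place of 1.22). Of 10 erythroid genes none had enough counts. All 3 measured genes of pluripotent stem cells fell (median −1.26), and LIN28A, an RNA-binding protein, fell 14.3-fold from 370.1 ± 2.53 to 25.9 ± 1.1 CPM, with ZFP42 and DPPA2 the others. Of 6 amnion genes, HEY1, ITGB6 and POSTN rose and BAMBI and WNT6 fell, with a median of 0.51, or 0.26 under library totals, a mean of 0.81 and camera pointing down without passing (adjusted p = 0.761). Of the 39 syncytiotrophoblast genes, 33 had at least 1 CPM in HTS and 6 stand in another list, none of them in the extravillous one. Of the 7 endothelial genes, 4 had at least 1 CPM in HTS.

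Among the largest rises outside these groups were ACAN, the cartilage proteoglycan aggrecan, from 0.125 ± 0.0828 to 68.2 ± 0.920 CPM, and PDE6H, a phosphodiesterase subunit known from the retina, from 0.0649 ± 0.0133 to 28.4 ± 0.827 CPM. ACAN and PDE6H had 15 and 7 counts in all of HTS. Among genes with at least 20 CPM in HTS, the largest fall was that of RTKN, a binding partner of Rho (chromosome 2, 74425836 to 74442422), from 67.8 ± 1.02 to 0.932 ± 0.629 CPM, 70.1-fold. The gap junction gene GJA1 fell 47.3-fold, the fatty acid binding protein FABP5 36.4-fold and the salt transporter SLC12A3 33.1-fold. PLCXD3 fell from 26.2 ± 0.947 to 0.788 ± 0.504 CPM, and the surface sialomucin PODXL fell 26.6-fold. BCAT1, which starts the breakdown of branched-chain amino acids, fell 24.2-fold and the transcription factor EGR3 23.1-fold. Without EVT replicate 3 the log2 fold changes were −6.89 for RTKN, −6.29 for GJA1, −5.70 for PLCXD3 and −5.76 for PODXL, against −6.13, −5.56, −5.00 and −4.74 with it.

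By the edgeR test, 13222 of the 17688 genes (74.8%) changed, 6589 up and 6633 down. At least 1.5-fold changes were found in 9319 genes, 4629 up and 4690 down, and at least 2-fold changes in 5904, with 2985 up and 2919 down. Scaling by library totals shifted the median log2 fold change of all genes from −0.01 to −0.25 and gave 4998 genes up and 8422 down, or 37.2% up in place of 49.8%. At 1.5-fold it gave 3519 up and 6208 down, or 36.2% up in place of 49.7%. With these summed libraries, HTS to 1 and EVT replicates 1 and 2 to 1, 8406 genes changed. Then no longer past the threshold were TP63 (log2 fold change −1.80 in place of −2.01), TFAP2C (0.56, 0.67), PODXL (−4.56, −4.74), COL1A2 (−2.06, −2.30) and CSF1R (1.36, 1.22). The same held for THBS1 (−3.54, −3.68), FLT4 (6.16, 6.44), SLCO2A1 (−2.44, −2.56), MT-ND2 (0.44, 0.51), MT-ND4 (0.42, 0.48), MT-ND5 (0.45, 0.51) and MT-ND6 (0.46, 0.51). Of the 39 lists tested, 22 passed with camera, and the syncytiotrophoblast and G2/M lists alone passed with an estimated correlation. List medians were the same with genes at their lower bound as with fitted values. The authors' deposited table lists 4418 genes past an absolute log2 fold change of 1.5, with 2467 higher and 1951 lower in EVT. Of these, 3518 were tested here with edgeR, and each was called in the direction given in the authors' deposited table. That table comes from the same libraries and holds only genes past its cutoffs. The match was thus bound to be close and is no independent support. The other 900 genes of the authors' deposited table had too few counts for the filter. Past both cutoffs of the authors' deposited table, edgeR found 3517 genes, 1864 up and 1653 down, of which 3505 are in it.

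Replicates lay close together except for EVT replicate 3. Between HTS libraries no gene of 10527, 11120 and 10698 compared was over 2-fold apart, and between EVT replicates 1 and 2 none of 9362. EVT replicate 3 was over 2-fold from replicate 1 in 116 of 9594 genes, such as the leptin gene LEP, singled out after its values were seen, at 1880 CPM against 5620. The first principal component separated EVT from HTS with 92.1% of the variance, and the second, with 4.2%, separated EVT replicate 3 from the other two. The p values measure only the spread between these libraries, which may be technical, and the cDNA kit keeps no strand, so levels of genes that overlap another gene are less certain. Of the 163 genes named by the rule, 65 share exonic bases with another gene, and 10 share at least 20% of their exonic length, among them HLA-G, CGB3, CYP11A1, PAPPA, IL6, XAF1 and ACE2.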

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

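The alternatives below were chosen before the data were examined, except the one that sums libraries. The number of genes changed was 13222 and stayed within 1.5 times of that under every alternative but the summed libraries: 13217 with DESeq2 size factors, 13420 with library totals, 14721 with no filter, 12016 with at least 1 CPM in 3 libraries, 12592 with DESeq2, 13311 with limma-voom, 12781 with thinned libraries, 13198 without the 20 most abundant and mitochondrial genes, 11399 at a threshold of 0.01, and 12335 to 14529 with 1 library left out. With the HTS libraries summed to 1 and EVT replicates 1 and 2 summed to 1, 8406 genes changed, 7970 of them shared with the full comparison, on fewer samples, with a spread from EVT alone. At 1.5-fold the range was 7997 to 10946, except that the test against a fold of 1.5 gave 7424, around 9319. Deviations of HTS and EVT libraries with the same number had correlations across genes of 0.004, 0.001 and 0.009. The HTS libraries differed little beyond counting error, so such values cannot tell whether the replicate numbers pair the samples. The replicate block gave 12853 changed genes and 22 lists.

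GATA2, at 0.02 without passing, changed sign and passed at −0.23 under library totals, which shift all genes by about that amount. KRT7 passed there at −0.29. Without EVT replicate 3, KRT7 passed at −0.08 and GATA2 at 0.11. With no filter TP63 (−2.07 in place of −2.01), COL1A2 (−2.37, −2.30) and CSF1R (1.15, 1.22) no longer passed, and with summed libraries 12 named genes no longer did: these 3, PODXL (−4.56, −4.74), TFAP2C, THBS1, FLT4 (6.16, 6.44), SLCO2A1 and 4 mitochondrially encoded ones. The other named genes kept their direction and their side of the threshold under each alternative they were tested in.

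Of 39 lists, 22 passed with camera, and 21 to 23 under the other scalings, with 1 library left out and with the block. With the 1 CPM filter, 37 lists could be tested and 20 passed. Of the 39, 2 passed with an estimated correlation and 36 with fry, which tests a list's own genes and not their difference from others. The unfolded protein list, at 0.0433, missed the threshold under library totals (0.141), the 1 CPM filter (0.0559), without each HTS library in turn (0.0506 to 0.0557), with the block (0.0621) and with summed libraries (0.138). The mitochondrially encoded list passed without EVT replicate 3 (0.00176). The cause of these changes was not tested. The count filter removed 900 genes of the authors' deposited table, while DESeq2 with no filter found 4402 genes past both cutoffs, 4335 of them in it.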

Other observations

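The tests of explanations in this part, and of other splits of the libraries, were chosen after the results were seen, while the gene lists and their tests were fixed beforehand. In each list the counts adjusted over the list alone were those given, unless both are stated, and genes named as a list's exceptions were singled out after their values were seen. Of 72 cytosolic ribosomal protein genes, 71 fell and none rose, with RPS10 not past the threshold (median −0.96, camera adjusted p = 1.04e-19; adjusted p = 0.298 with an estimated correlation), with RPSA at 3.06-fold and RPL24 at 2.67-fold lower. In EVT replicate 3, 66 of the 72 were below both other EVT libraries (median log2 ratio −0.14). Of 72 nuclear-encoded genes of oxidative phosphorylation, 62 fell and 3 rose, against 63 and 3 adjusted over the list alone (median −0.53, camera adjusted p = 3.69e-06; adjusted p = 0.25 with an estimated correlation). NDUFS6, a complex I subunit, fell 4.67-fold, and NDUFA6, NDUFB1 (0.25) and NDUFB5 (0.30) rose. Of the 13 mitochondrially encoded genes, 8 rose and none fell (median 0.27, camera adjusted p = 0.31; adjusted p = 0.844 with an estimated correlation), but 5 rose and 5 fell under library totals (median 0.03). All 13 were lowest in replicate 3 of the EVT libraries (median log2 ratio −0.18), and the list passed without that library (adjusted p = 0.00176, in a range of 0.00176 to 0.581 at the preset correlation). MT-ND2, a complex I subunit, rose 1.43-fold. Glycolysis genes fell, 15 of 20 with 5 rising (median −0.80, camera adjusted p = 0.00702; adjusted p = 0.273 with an estimated correlation). Among them were the glucose transporter SLC2A3 (4-fold lower), the phosphofructokinase PFKP (3.83-fold) and the lactate dehydrogenase LDHA (2.68-fold), while SLC2A1, HK2, ALDOC, PFKL and SLC16A3 rose. Of 33 hypoxia-induced genes, 17 rose and 10 fell (median 0.25, camera adjusted p = 0.661), but 12 and 12 under library totals (median 0.00). The vasodilator peptide gene ADM rose 6.57-fold. Of 29 solute and amino acid transporters, 15 rose and 11 fell (median 0.42, camera adjusted p = 0.109), or 15 and 13 under library totals (median 0.17), and the noradrenaline transporter SLC6A2 rose 64.8-fold. SLCO2A1, a prostaglandin transporter, fell, and its log2 fold change of −2.56 became −3.16 without EVT replicate 3.

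Histone genes read in these libraries rose, 11 of 16 with 2 falling, against 12 and 2 adjusted over the list alone (median 1.81, camera adjusted p = 0.000163; adjusted p = 0.259 with an estimated correlation). The linker histone HIST1H1C rose 21.8-fold and HIST1H2AC 18.4-fold, and the variant histone genes H2AFZ and H3F3B fell. The summed level of the list moved less, from 744.5 CPM in HTS to 918.7 CPM in EVT. These values cover only the histone transcripts that the cDNA kit captured, a share that was not measured. They do not give the level of all histone transcripts. Of the 16, 11 were lower in EVT replicate 3 than in both other EVT libraries (median log2 ratio −0.18). Chromatin regulators went both ways, with 16 of 34 up and 13 down (median −0.03, camera adjusted p = 0.843), but 13 up and 17 down under library totals (median −0.27). The DNA methyltransferase DNMT3B fell 5.98-fold and the deacetylase HDAC5 rose 6.94-fold. Of these 34, 25 were lower in EVT replicate 3 than in both other EVT libraries (median log2 ratio −0.12). Of 26 imprinted genes, 14 rose and 6 fell (median 0.35, camera adjusted p = 0.29), but 11 and 10 under library totals (median 0.11). PEG10, a retrotransposon-derived placental gene, fell 13.8-fold and its neighbour SGCE 9.60-fold. Of 33 lysosome and autophagy genes, 20 rose and 7 fell (median 0.29, camera adjusted p = 0.00196; adjusted p = 0.298 with an estimated correlation), but 16 and 10 under library totals (median 0.04). The autophagy kinase ULK1 rose 13.5-fold and the protease CTSL 4.38-fold. Of 31 genes of the unfolded protein and integrated stress response, 21 rose and 5 fell (median 0.36, camera adjusted p = 0.0433; adjusted p = 0.298 with an estimated correlation), but 15 and 9 under library totals (median 0.11). That call was lost under library totals (0.141), with a filter of 1 CPM (0.0559), without HTS replicate 1 (0.0557), 2 (0.0536) or 3 (0.0506), with the replicate number as a block (0.0621) and with libraries summed after their closeness was seen (0.138), in a range of 0.0024 to 0.141 over its alternatives at the preset correlation. Of the 31, 20 were lower in EVT replicate 3 than in both other EVT libraries (median log2 ratio −0.08). CRELD2, an endoplasmic reticulum protein, rose 6.02-fold, and ATF3, DNAJC3, MTHFD2, PSAT1 and SLC7A11 fell. Sterol synthesis genes split evenly, with 8 of 23 up and 8 down (median −0.06, camera adjusted p = 0.845), but 4 up and 13 down under library totals (median −0.31). Of the 23, 14 were higher in EVT replicate 3 than in both other EVT libraries (median log2 ratio 0.14). The LDL receptor gene LDLR rose 1.84-fold.

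Syncytiotrophoblast genes were higher in the EVT libraries by a median log2 fold change of 4.37. Reads shared between near-identical copies are argued against, since the 17 members without such a copy had a median of 3.71 (quartiles 2.02 and 4.64) and 16 of them rose. A scaling moved by a few abundant genes is argued against as well, since the lowest median over 3 scalings and without the 20 most abundant genes was 4.13. A mixed culture in which some cells became syncytiotrophoblast cannot be told apart from cells that carry both programmes, because the libraries are bulk and only 1 stands apart: between EVT replicate 3 and the other two the log2 ratio of 37 members had an SD of 0.55, from −1.59 for LEP to 0.93. The differentiation itself, which is the difference between the groups, stays open as the biological explanation and was not tested apart from these. Any culture conditions that differ between the groups cannot be told apart from the differentiation.

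EVT replicate 3 stood apart, with interferon-stimulated genes lower and mesenchymal and protease inhibitor genes higher than in replicates 1 and 2. Among genes singled out after their values were seen, AXL was at 0.949, 0.854 and 11.9 CPM and IFIT1 at 133, 140 and 60.1 CPM in replicates 1, 2 and 3. Depth is argued against, since 114 of 9313 genes stayed over 2-fold apart between replicates 1 and 3 after thinning to a common total, against 0 between replicates 1 and 2. Stem-state cells left in the culture are argued against as the whole cause, since 44 of the 61 higher genes lie above every HTS library. The 23 genes at least 16-fold higher in HTS allow a median share of 3.59% stem-state RNA (upper quartile 5.62%), while 17 of the genes higher in replicate 3 need 33.9% (lower quartile 23.0%). Those 17 were chosen for being over 2-fold higher there, which in itself raises the share needed, so no conclusion is drawn from the 2 shares. Less advanced differentiation cannot be told apart from other causes, since 69 of 109 moved genes (63.3%) lay towards HTS while the 36 risen extravillous members had a median log2 ratio of 0.23 (quartiles −0.06 and 0.63), and the design, which names no difference between replicates, gives no biological explanation to test.

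The HTS libraries were nearly as close to each other as counting allows. The spread per library over abundant genes was 2.07% between HTS replicates 1 and 3, where counting alone gives 1.96%, 2.87% between EVT replicates 1 and 2, where it gives 2.11%, and 9.97% between EVT replicates 2 and 3, where it gives 2.09%. Libraries of 1 RNA sample or culture cannot be told apart from separate but very similar cultures, because no library known to come from a separate culture is at hand, and no biological explanation was tested, since the design gives none within a group. The same holds for 1 library sequenced more than once, for which a chi-square per gene of 1 is needed and the largest between HTS libraries was 1.34 (summed chi-square over 16460 genes, p = 5.15e-171). The other HTS pairs, at 1.3 and 1.29, lay above 1 as well (chi-square p = 7.5e-129 and 3.39e-126), but estimated counts may add such an excess by an amount that was not measured.

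The 6 libraries can be split 3 against 3 in 10 ways, of which 1, the real one, gave 13222 changed genes with edgeR, and the highest count among the other 9 was 0, with at most 91 genes at an unadjusted p under 0.05. DESeq2 and limma-voom also gave at most 0 genes in the other splits. Each of the other 9 splits puts HTS and EVT libraries on both sides, so the difference between the groups widens the spread there. Their counts were thus bound to be low and do not speak against chance. With 10 splits the share of splits also cannot go under 0.05.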
